A study of Mus musculus with 50 samples.

How the data were processed

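RNA was extracted with the AllPrep DNA/RNA kit, libraries were made with the TruSeq stranded mRNA kit and sequenced as 150 nt paired-end reads on a NovaSeq instrument, per the labels. Per the submitters' processing notes, reads were processed with STAR 2.7.10b, Bowtie2 2.3.4.1, RSEM 1.3.1 and SAMtools 1.9 against mm10, and the values used here were the gene TPM deposited by the authors in 2 tables, 18 and 32 columns wide. Which tool made which step, the gene annotation and the handling of reads that map to several copies are not given in the sources used here. The first table held a Dux row and the second held rows for the TetOnDux transgene and the MERVL-sfGFP reporter. The 2 tables were normalised separately and never compared sample by sample, and raw reads were not used here. All 50 samples were matched to a column by the column names in the labels, and columns without a sample numbered 0.

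Values were analysed as log2(TPM+1) in R 4.3.3 with limma 3.58.1 and data.table version 1.17.8. Genes at 1 TPM or more in at least 2 libraries of a table were tested, 13862 in the first and 13817 in the second, of which 39 and 41 had values identical to another gene in every library. All groups of either table entered a linear model of their own without covariates, with a trend of the variance on the mean, so that they shared an estimate of the spread (9 and 16 residual degrees of freedom), and p-values were adjusted by Benjamini-Hochberg over the genes of each comparison. A gene was called at an adjusted p below 0.05 and an absolute log2 fold change of at least 1. Interactions were differences of differences in the same model, and doxycycline responses were compared between lines of the same dose label alone. Errors are SD between the 2 libraries of a group, or the standard error of the model for a log2 fold change.

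Gene lists were written before the data were examined: 2-cell and Dux-linked, Obox, germline, pluripotency, trophoblast, primitive endoderm, germ layer and epiblast, imprinted, p53 target, ATF4 stress response, interferon response, H3K9 and silencing machinery, fibroblast, proteasome (as a comparator) and targeted genes. The Dux-induced set was defined by rule from the doxycycline response of the control line. Lists were tested with limma camera at a preset correlation between genes of 0.01, adjusted over all lists and comparisons of a table, and again with an estimated correlation and with limma fry. Members were counted as higher, lower or not called, over all genes and adjusted over the list alone, and where 1 pair of counts is given the 2 ways gave the same counts. Genes named in the text were the targeted genes, then called genes whose libraries did not overlap between the groups, by size of the log2 fold change, leaving out predicted gene names, then called members of each list and 2 uncalled members of the highest TPM. Overlap between the tables was described with Fisher's exact test. Coordinates and transcript lengths came from GENCODE M21 (GRCm38), which held 13728 of the 14263 tested genes.

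Alternatives were a pseudocount of 0.1, no filter on low values, scaling by median ratios, the replicate number as a block and each library left out in turn. After seeing the data, the second table was also fitted without its 6 libraries of high nuclear RNA, defined by a mean log2 level of Snhg genes above 4, and with that class as a term, and with 2 settings based on a split in Snrpn. In a test, log2 changes of 1.5, 2 and 3 were put into simulated noise, and not all changed genes were scored. For QKO against control 50 of 50, 53 of 54 and 49 of 50 were recovered, with 0 of 13662 unchanged genes called. For doxycycline in control 45 of 53, 46 of 48 and 53 of 53 were, with 5 of 13617 called. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Repeat elements, single transcripts and splicing were not analysed here.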

Results

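RNA was measured by poly(A)-selected, stranded sequencing of mouse embryonic stem cells of strain TT2 in 50 libraries, 2 for each of 25 groups. The groups asked what embryonic stem cells transcribe when they lack enzymes that methylate lysine 9 of histone H3: Setdb1, Suv39h1 with Suv39h2, and G9a, the product of Ehmt2. A first table of 18 libraries held control cells, 7 combinations of these losses up to the loss of all 4 genes (QKO, for G9a Suv39h1/2 Setdb1-QKO), and QKO cells that also lacked Dux, the homeobox gene that opens the 2-cell program of the mouse embryo (Dux-KO QKO). A second table of 32 libraries held the same 8 genotypes in cells that carried a doxycycline-inducible Dux transgene, each without and with doxycycline (dose label 0.2 for control and Setdb1-KO, 1 for the other 6 genotypes, unit not given). The loss of endogenous Dux in these cells stood in the genotype field of all 32 libraries but not in their titles, and no row of this table measured it. Titles of all groups without Setdb1 carried OHT and those of all other groups NT, 2 abbreviations the labels do not explain, so what OHT stands for cannot be told apart from Setdb1 loss. Values were TPM (transcript abundances scaled to a fixed total) deposited by the authors, so sequencing depth was not known, and 11855 to 13274 genes per library reached 1 TPM in the first table against 11742 to 12690 in the second. Groups were compared within a table with limma, and a gene was called at an adjusted p below 0.05 and an absolute log2 fold change of at least 1, a rule written before the data were examined. The labels did not call the 2 replicates of a group separate cultures, so every p-value measured the spread between these samples.

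The targeted genes were read first, in every library (n = 2 per group throughout, SD in parentheses). Setdb1 (chr3:95323525-95357202, GRCm38) lay at 51 (SD 3.08) TPM in control libraries, at 22.9 (SD 4.38) in Setdb1-KO (log2 fold change -1.14, SE 0.144, adjusted p = 3.61e-05), 24.8 (SD 3.11) in Suv39h1/2 Setdb1-TKO, 29.1 (SD 4.72) in G9a Setdb1-DKO, 27.8 (SD 1.43) in QKO and 35.1 (SD 2.00) in Dux-KO QKO. It stood between 43.8 and 46.5 TPM in the 3 genotypes that kept it. Ehmt2 (chr17:34898469-34914052) fell from 87.3 (SD 5.33) TPM to 15.1 (SD 0.733) in G9a-KO (-2.46, SE 0.132, adjusted p = 3.02e-09), 7.43 (SD 0.0647) in G9a Setdb1-DKO, 26.5 (SD 5.31) in G9a Suv39h1/2-TKO and 17.2 (SD 0.674) in QKO, and lay at 13.3 (SD 1.25) in Dux-KO QKO. Suv39h1 (chrX:8061171-8074760) was at 32.8 (SD 1.63) TPM in control, 22.6 (SD 0.358) in Suv39h1/2-DKO, 18.9 (SD 2.65) in Suv39h1/2 Setdb1-TKO, 13.6 (SD 1.08) in G9a Suv39h1/2-TKO, 11.3 (SD 0.289) in QKO and 12.6 (SD 0.115) in Dux-KO QKO, but also at 23.1 (SD 2.51) in G9a Setdb1-DKO, which kept it. Suv39h2 (chr2:3455815-3475031) was at 20.9 (SD 0.219) TPM in control and at 14.4 (SD 0.601), 16.1 (SD 1.44), 12.7 (SD 0.908), 14.8 (SD 2.11) and 13.98 (SD 0.611) in the same 5 genotypes. Suv39h1 and Suv39h2 were not called in Suv39h1/2-DKO (log2 fold change -0.52, SE 0.127, adjusted p = 0.0505 and -0.51, SE 0.152, adjusted p = 0.13). Residual transcript of a targeted gene gives no protein level, and none was measured here.

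**Figure D1:**
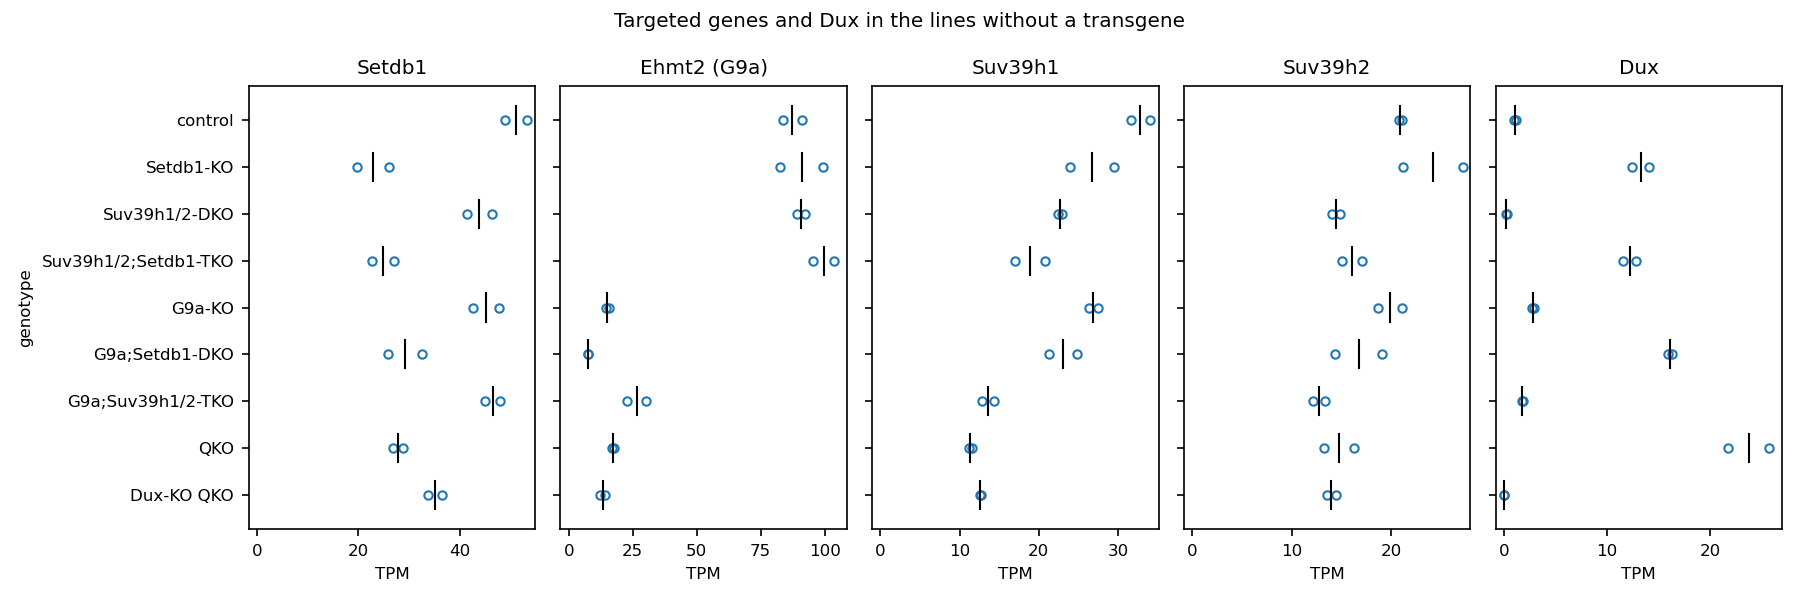
TPM of Setdb1, Ehmt2, Suv39h1, Suv39h2 and Dux in each of the 18 libraries of the first table. Open circles are libraries and bars are group means, n = 2 per group.

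Dux itself was read at 1.06 (SD 0.124) TPM in control cells and rose with every loss that included Setdb1. It reached 13.3 (SD 1.13) TPM in Setdb1-KO (log2 fold change 2.79, SE 0.12, adjusted p = 2.89e-10) and 12.2 (SD 0.886) in Suv39h1/2 Setdb1-TKO (2.68, SE 0.12, adjusted p = 5.42e-10). With G9a lost too it reached 16.1 (SD 0.289) in G9a Setdb1-DKO (3.06, SE 0.12, adjusted p = 2.84e-11) and 23.8 (SD 2.78) in QKO (3.59, SE 0.12, adjusted p = 4.51e-12). Without Setdb1 loss it was at 0.236 (SD 0.0418) TPM in Suv39h1/2-DKO, 2.83 (SD 0.107) in G9a-KO (0.90, SE 0.12, adjusted p = 3.89e-05) and 1.80 (SD 0.0545) in G9a Suv39h1/2-TKO (0.45, SE 0.12, adjusted p = 0.0118). Both Dux-KO QKO libraries were listed at 0. Dux is a gene of many near-identical copies, and how reads were divided between copies is not given in the sources used here.

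What changes when Setdb1 alone is lost was asked first, and 571 genes were higher and 300 lower in Setdb1-KO than in control libraries (limma, Benjamini-Hochberg, n = 2 per group). Genes of the 2-cell embryo rose together, with 39 of 51 higher and 0 lower (median 2.7, adjusted p = 2.07e-46) in the 2-cell and Dux-linked list by limma camera. Zscan4d, of a family that acts on telomeres in 2-cell embryos, rose from 6.86 (SD 0.00894) to 236 TPM (SD 16.9) (log2 fold change 4.91, SE 0.188, adjusted p = 9.63e-11). Usp17lb (0.823 to 46.4 TPM, 4.71, SE 0.119) did too. Obox4, a homeobox gene of oocytes and early embryos, rose from 3.93 (SD 0.221) to 75.3 TPM (SD 8.83) (3.95, SE 0.142, adjusted p = 5.37e-11), with 2 of 4 higher and 0 lower (median 1.02, adjusted p = 0.000397) in the Obox family. Copies of Zscan4, Usp17l, Tdpoz, Obox, Tcstv, Pramel, Magea and Duxbl genes are near identical, so here and below each of these names is uncertain between copies. The largest rises outside these families were Akr1c21 (0.948 to 106 TPM, 5.79, SE 0.146) and Mmp12 (0.465 to 71.9 TPM, 5.64, SE 0.0967).

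Germline genes, many of which other cells keep silent, also rose in Setdb1-KO, 28 of 38 higher and 0 lower (median 1.41, adjusted p = 3.09e-26). Not all of them were silent in the control cells here. They included Tex101, a germ cell surface protein, from 0.884 (SD 0.00879) to 79.6 TPM (SD 2.11) (log2 fold change 5.42, SE 0.126, adjusted p = 6.92e-13), Stk31 (7.10 to 77.0 TPM, 3.26, SE 0.162), and Mael (6.02 to 63.7 TPM, 3.20, SE 0.114), a piRNA pathway gene. Targets of p53 had 8 of 20 higher and 0 lower (median 0.73, adjusted p = 9.66e-10, adjusted p = 0.0545 with an estimated correlation), led by Trp53inp1 (38.7 to 113 TPM, 1.49, SE 0.269) and Plk2 (19.5 to 55.7 TPM, 1.46, SE 0.141). Otx2, a homeobox gene of the primed epiblast, rose from 5.08 (SD 0.0599) to 61.0 TPM (SD 6.59) (3.35, SE 0.13, adjusted p = 1.07e-10), while its list of germ layer and epiblast genes had 1 of 10 higher and 1 lower (adjusted p = 0.729). Of the pluripotency genes, 0 of 25 were higher and 3 lower (median -0.24, adjusted p = 0.27). Prdm14 (20.1 to 7.12 TPM, -1.38, SE 0.137) and Klf4 (154 to 61.5 TPM, -1.31, SE 0.12) fell, and Pou5f1, the Oct4 gene, was at 2417 against 2280 TPM (0.08, SE 0.074, adjusted p = 0.4). The largest fall was that of Msc, from 49.3 (SD 5.44) to 4.08 TPM (SD 1.47) (-3.34, SE 0.194, adjusted p = 8.3e-09). The proteasome genes taken as a comparator counted 0 of 31 higher and 0 lower (median 0.02, adjusted p = 0.408). Scaling to median ratios moved the all-gene median log2 fold change from -0.12 to 0.03 and the share of called genes that were higher from 65.6% to 80%.

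Loss of Suv39h1 and Suv39h2 alone asked the same of the enzymes of pericentromeric heterochromatin, and 19 genes were higher and 56 lower than control (limma, n = 2 per group). Here genes of the 2-cell embryo fell, with 0 of 51 higher and 18 lower (median -0.75, adjusted p = 1.41e-37) in the 2-cell list. Zscan4f fell from 35.3 (SD 4.09) to 2.93 TPM (SD 0.757) (log2 fold change -3.22, SE 0.142, adjusted p = 1.86e-08), as did Zscan4c (20.9 to 2.00 TPM, -2.88, SE 0.154). Obox4 fell from 3.93 (SD 0.221) to 0.496 TPM (SD 0.0526) (-1.72, SE 0.142, adjusted p = 5.24e-06). Genes of primitive endoderm, the extraembryonic layer marked by Gata4 and Gata6, had 2 of 19 higher and 0 lower (median 0.75, adjusted p = 3.06e-22), with Srgn (24.2 to 57.6 TPM, 1.22, SE 0.12), a granule proteoglycan, and Dab2 (10.3 to 24.2 TPM, 1.16, SE 0.139), an endocytic adaptor. Other rises were those of S100g (2.12 to 9.30 TPM, 1.74, SE 0.168) and Fst (2.02 to 7.02 TPM, 1.41, SE 0.14). Of 30 imprinted genes, 0 were higher and 1 was lower, the growth inhibitor Cdkn1c (16.2 to 6.75 TPM, -1.14, SE 0.152). ATF4 stress response genes counted 0 of 16 higher and 0 lower (median 0.15, adjusted p = 4.09e-06, adjusted p = 0.0543 with an estimated correlation).

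Cells without G9a, the H3K9 dimethylation enzyme, had 765 genes higher and 519 lower than control (limma, n = 2 per group). The 2-cell list rose here too, 40 of 51 higher and 0 lower (median 1.83, adjusted p = 5.98e-29), with Usp17lb (0.823 to 22.7 TPM, log2 fold change 3.70, SE 0.119). Obox4 rose from 3.93 (SD 0.221) to 36.1 TPM (SD 1.46) (2.91, SE 0.142, adjusted p = 1.12e-09). X-linked Magea genes, silent outside the male germline, were among the largest rises: Magea8 went from 0.0258 (SD 0.0365) to 175 TPM (SD 15) (7.42, SE 0.131, adjusted p = 2.1e-14) and Magea2 from values listed at 0 to 116 TPM (SD 18.3). Imprinted genes had 11 of 30 higher and 2 lower (median 0.64, adjusted p = 1.1e-07, adjusted p = 0.126 with an estimated correlation). They were led by the maternally expressed non-coding RNAs of chromosome 12: Rian went from 0.183 (SD 0.111) to 83.4 TPM (SD 3.87) (6.16, SE 0.119, adjusted p = 5.08e-14). Meg3 (chr12:109541001-109571726) went from 0.0340 (SD 0.0408) to 64.7 TPM (SD 7.05) (5.99, SE 0.175, adjusted p = 3.52e-12). H19 (2.81 to 98.6 TPM, 4.71, SE 0.109) and Peg3 (4.67 to 112 TPM, 4.31, SE 0.194) followed.

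Primitive endoderm genes rose nearly as a whole in G9a-KO libraries, 18 of 19 higher and 0 lower (median 2.32, adjusted p = 1.44e-17, adjusted p = 0.0742 with an estimated correlation). The transcription factor genes Gata4 (12.9 to 89.0 TPM, log2 fold change 2.69, SE 0.143) and Gata6 (17.6 to 91.8 TPM, 2.32, SE 0.128) were among them. Pdgfra rose from 6.10 (SD 0.201) to 53.8 TPM (SD 1.06) (2.95, SE 0.189, adjusted p = 2.01e-08). Srgn (24.2 to 203 TPM, 3.01, SE 0.12) and Lama1 (27.9 to 207 TPM, 2.84, SE 0.228) did too. Germline genes had 9 of 38 higher and 3 lower (median 0.21, adjusted p = 0.0182, adjusted p = 0.465 with an estimated correlation), with Asz1 (0.0876 to 17.3 TPM, 4.07, SE 0.154) and Rpl10l (25.8 to 244 TPM, 3.19, SE 0.095), a testis copy of a ribosomal protein gene. Of the pluripotency genes, 1 of 25 was higher and 2 lower (median -0.22, adjusted p = 0.0326, adjusted p = 0.518 with an estimated correlation). Dppa3 (4.71 to 31.98 TPM, 2.54, SE 0.173) rose. Nr5a2 (44.5 to 18.6 TPM, -1.21, SE 0.212) and Esrrb (349 to 169 TPM, -1.04, SE 0.143) fell.

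With Setdb1 lost on top of Suv39h1 and Suv39h2, 657 genes were higher and 312 lower than control (limma, n = 2 per group). In the 2-cell list 34 of 51 were higher and 0 lower (median 1.94, adjusted p = 2.44e-33), and Zscan4d rose from 6.86 (SD 0.00894) to 161 TPM (SD 1.28) (log2 fold change 4.36, SE 0.188, adjusted p = 3.69e-10). Cd209c (1.35 to 147 TPM, 5.98, SE 0.12), Akr1c21 (0.948 to 106 TPM, 5.79, SE 0.146) and the germ cell gene Tex101 (0.884 to 58.6 TPM, 4.98, SE 0.126) were among the largest rises. Germline genes had 28 of 38 higher and 0 lower (median 1.64, adjusted p = 1.11e-23) and p53 targets 8 of 20 higher and 0 lower (median 0.90, adjusted p = 4.57e-11). Of the primitive endoderm genes, 8 of 19 were higher and 0 lower (median 0.91, adjusted p = 5.93e-09, adjusted p = 0.218 with an estimated correlation). Falls were led by Msc (49.3 to 2.91 TPM, -3.69, SE 0.194) and Ccnd1 (41.4 to 5.72 TPM, -2.66, SE 0.126).

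Without G9a and Setdb1, 1328 genes were higher and 665 lower (limma, n = 2 per group). Nearly every measured gene of the 2-cell list rose, 50 of 51 higher and 0 lower (median 4.59, adjusted p = 1.19e-39). Usp17lb rose from 0.823 (SD 0.196) to 252 TPM (SD 9.3) (log2 fold change 7.12, SE 0.119, adjusted p = 9.44e-15) and Obox4 from 3.93 (SD 0.221) to 193 TPM (SD 37.7) (5.29, SE 0.142, adjusted p = 6.48e-13). Zscan4d went from 6.86 (SD 0.00894) to 324 TPM (SD 12.4) (5.37, SE 0.188, adjusted p = 7.79e-12). Magea8 (0.0258 to 190.2 TPM, 7.54, SE 0.131) and the imprinted Rian (0.183 to 129 TPM, 6.77, SE 0.119) and Meg3 (0.0340 to 112 TPM, 6.77, SE 0.175) were among the largest rises. Germline genes had 23 of 38 higher and 1 lower (median 1.45, adjusted p = 6.12e-12). Primitive endoderm genes counted 16 of 19 higher and 0 lower (median 1.41, adjusted p = 1.04e-08, adjusted p = 0.226 with an estimated correlation). p53 targets had 9 of 20 higher and 0 lower (median 0.84, adjusted p = 1.31e-07, adjusted p = 0.0858 with an estimated correlation). Islr2, from 37.6 (SD 2.57) to 1.42 TPM (SD 0.18) (-3.995, SE 0.18, adjusted p = 1.43e-10), and Igsf21 (28.6 to 1.53 TPM, -3.56, SE 0.212) fell most.

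Without G9a, Suv39h1 and Suv39h2, but with Setdb1 in place, 645 genes were higher and 287 lower (limma, n = 2 per group). H19 rose from 2.81 (SD 0.157) to 169.9 TPM (SD 17.2) (log2 fold change 5.49, SE 0.109, adjusted p = 2.46e-13). So did Magea8 (0.0258 to 27.9 TPM, 4.81, SE 0.131) and Rian (0.183 to 29.4 TPM, 4.69, SE 0.119). Markers of primitive endoderm had 17 of 19 higher and 0 lower (median 2.26, adjusted p = 2.37e-20, adjusted p = 0.0549 with an estimated correlation). Among them were Dab2 (10.3 to 120.2 TPM, 3.43, SE 0.139) and Pdgfra (6.10 to 53.6 TPM, 2.94, SE 0.189). In the 2-cell list 35 of 51 were higher and 0 lower (median 1.61, adjusted p = 7.12e-27), with Obox4 at 29.9 TPM (2.65, SE 0.142, adjusted p = 5.6e-09). Imprinted genes counted 8 of 30 higher and 3 lower (median 0.45, adjusted p = 2.49e-05, adjusted p = 0.229 with an estimated correlation). Pnp2 (chr14:50955992-50964749) was at 14.8 TPM (SD 1.33) in control and listed at 0 in both libraries of this genotype. Rpph1 (23.4 to 0.738 TPM, -3.95, SE 0.428) and Islr2 (37.6 to 4.19 TPM, -2.93, SE 0.18) fell.

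Loss of all 4 genes together was asked for next, and 1406 genes were higher and 751 lower in QKO than in control (limma, Benjamini-Hochberg, n = 2 per group). The 2-cell list rose to the highest median of the 7 genotypes, 49 of 51 higher and 0 lower (median 5.51, adjusted p = 1.19e-39). Usp17lb rose from 0.823 (SD 0.196) to 540.2 TPM (SD 2.75) (log2 fold change 8.22, SE 0.119, adjusted p = 2.26e-15) and Obox4 from 3.93 (SD 0.221) to 774 TPM (SD 96.4) (7.29, SE 0.142, adjusted p = 2.27e-14). Zscan4d (chr7:11161374-11166159) went from 6.86 (SD 0.00894) to 646 TPM (SD 51.7) (6.36, SE 0.188, adjusted p = 1.31e-12). All of the measured Obox genes rose, 4 of 4 higher and 0 lower (median 2.01, adjusted p = 0.000111). Outside these families the steroid enzyme Akr1c21 (0.948 to 436 TPM, 7.82, SE 0.146), the collagenase Mmp1b (0.0334 to 124 TPM, 6.90, SE 0.16) and the imprinted Meg3 (0.0340 to 56.9 TPM, 5.79, SE 0.175) and Rian (0.183 to 58.2 TPM, 5.65, SE 0.119) were among the largest rises. Germline genes had 28 of 38 higher and 1 lower (median 1.91, adjusted p = 3.92e-15), with Asz1 (0.0876 to 17.5 TPM, 4.09, SE 0.154) and Stk31 (7.10 to 112 TPM, 3.79, SE 0.162) higher. The 1 germline gene that fell was Stra8, the retinoic acid target that starts meiosis, from 338 (SD 10.4) to 23.2 TPM (SD 3.58) (-3.82, SE 0.0981, adjusted p = 2.83e-13).

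p53 targets in QKO had 13 of 20 higher and 0 lower (median 1.02, adjusted p = 4.41e-08, adjusted p = 0.0752 with an estimated correlation), led by Trp53inp1 (38.7 to 296 TPM, log2 fold change 2.90, SE 0.269) and Btg2 (12.6 to 77.8 TPM, 2.54, SE 0.111). Of the pluripotency genes, 5 of 25 were higher and 1 lower (median 0.18, adjusted p = 0.272), with Dppa5a (3088 to 7845 TPM, 1.34, SE 0.123) higher and Pou5f1 at 2095 against 2280 TPM (-0.12, SE 0.074, adjusted p = 0.175). ATF4 genes counted 3 of 16 higher and 6 lower (median -0.76, adjusted p = 0.011, adjusted p = 0.264 with an estimated correlation), with the glutathione-degrading Chac1 (14.8 to 2.24 TPM, -2.28, SE 0.145) and the serine synthesis gene Phgdh (113 to 25.6 TPM, -2.11, SE 0.115) lower. Imprinted genes had 12 of 30 higher and 3 lower (median 0.78, adjusted p = 0.000197, adjusted p = 0.281 with an estimated correlation). Trophoblast genes counted 5 of 16 higher and 1 lower (median 0.51, adjusted p = 0.0128, adjusted p = 0.281 with an estimated correlation). The primitive endoderm list had 3 of 19 higher and 0 lower (median 0.59, adjusted p = 0.00432, adjusted p = 0.542 with an estimated correlation). Otx2 (5.08 to 80.8 TPM, 3.75, SE 0.13) rose among germ layer genes, whose list had 2 of 10 higher and 3 lower (median 0.20, adjusted p = 0.611). Interferon response genes had 2 of 11 higher and 0 lower (median 0.43, adjusted p = 0.277). Fibroblast genes, markers of feeder cells, had 2 of 11 higher and 2 lower (median 0.13, adjusted p = 0.779). The H3K9 and silencing machinery had 2 of 29 higher and 2 lower (median -0.36, adjusted p = 0.0313, adjusted p = 0.783 with an estimated correlation). The proteasome comparator had 0 of 31 higher and 0 lower (median -0.25, adjusted p = 0.00205, adjusted p = 0.106 with an estimated correlation). Its camera p-value was below those of the ATF4, trophoblast, primitive endoderm and silencing machinery lists, so theirs do not set these lists apart from the comparator. Beside Stra8, the largest falls were those of Pnp2, from 14.8 (SD 1.33) to 0.121 TPM (SD 0.17) (-3.83, SE 0.179, adjusted p = 2.27e-10), Islr2 (37.6 to 1.92 TPM, -3.73, SE 0.18) and Ccnd1 (41.4 to 2.60 TPM, -3.56, SE 0.126). Scaling to median ratios moved the all-gene median from -0.05 to 0.07.

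**Figure D2:**
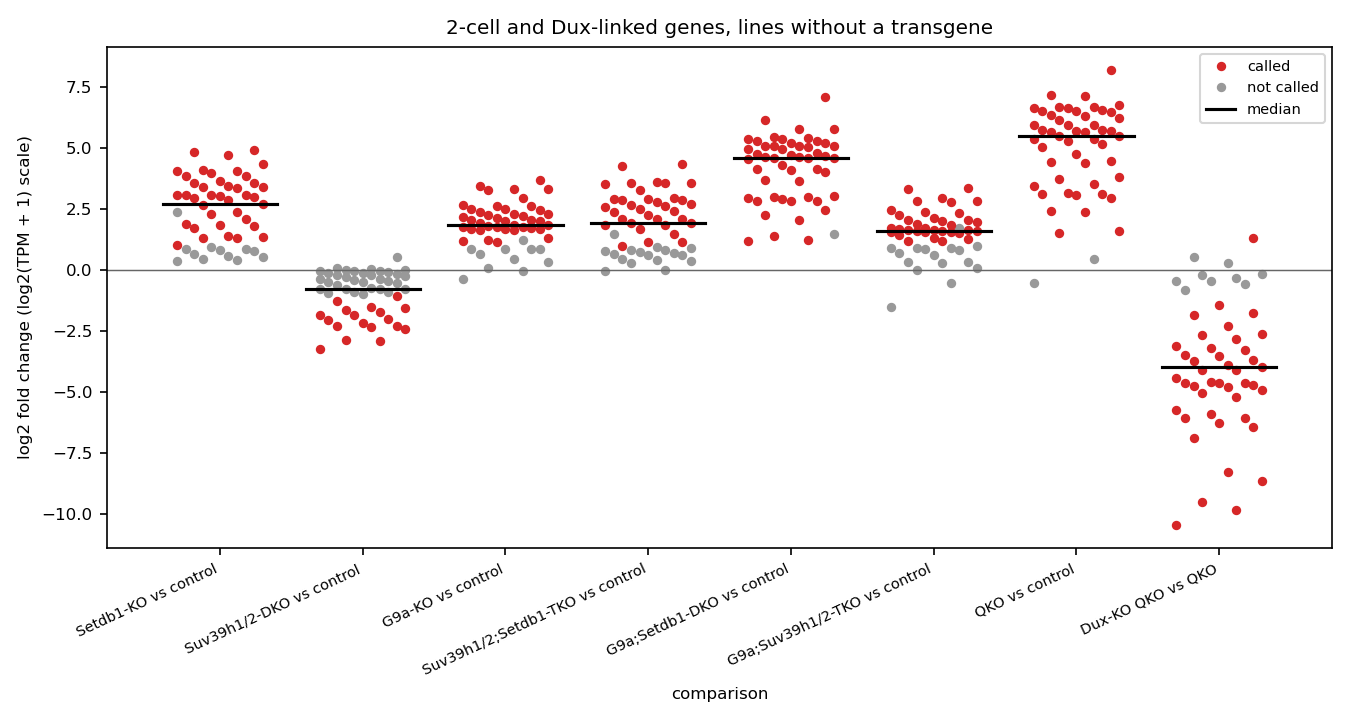
Log2 fold changes of the 51 measured genes of the 2-cell and Dux-linked list in the comparisons of the first table. Red points were called, grey points were not, and black lines are medians.

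**Figure D3:**
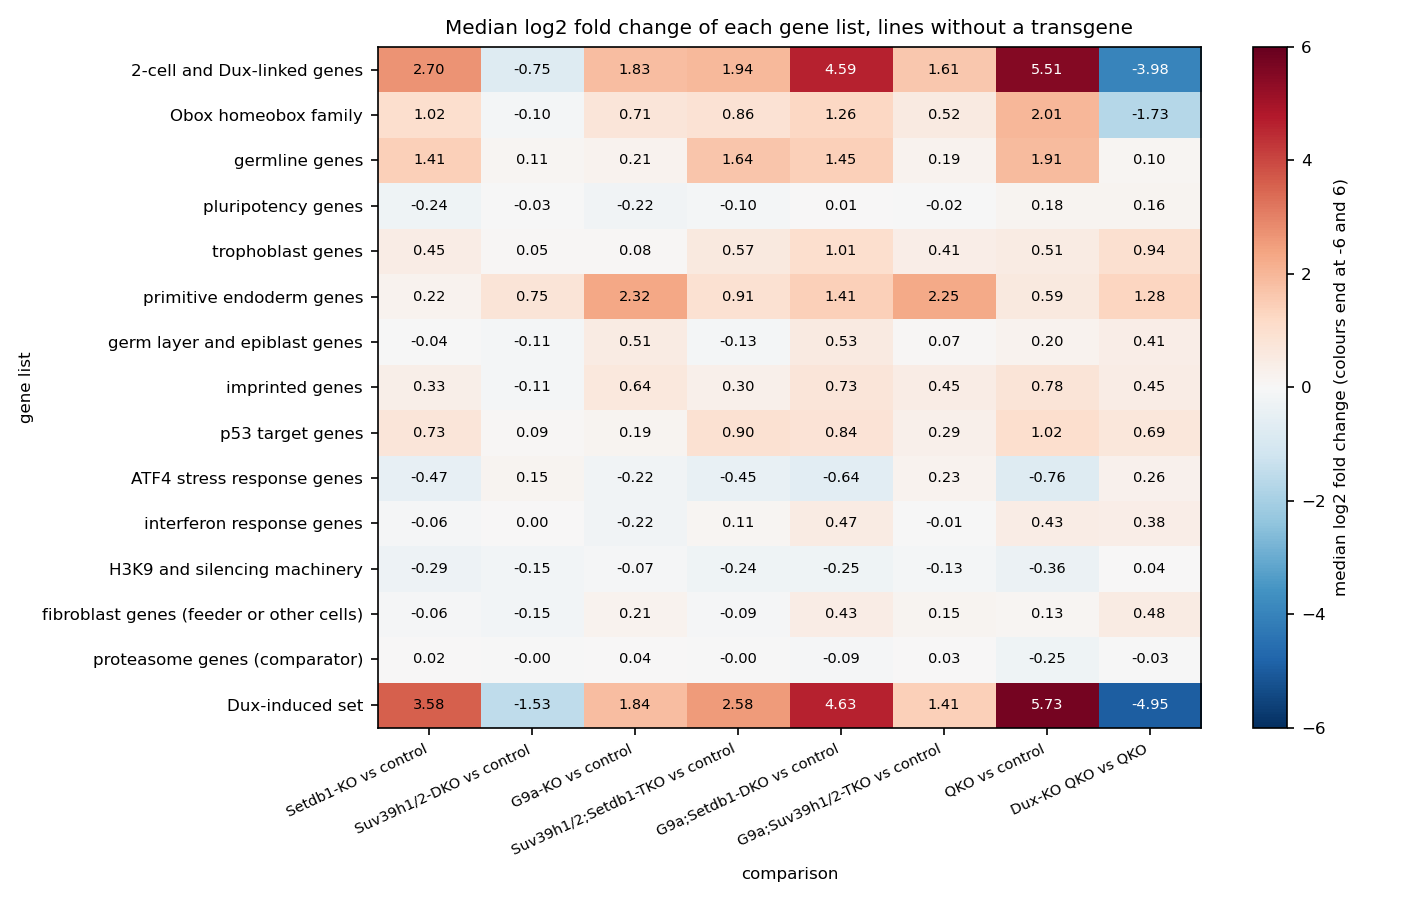
Median log2 fold change of each of 15 gene lists in 8 comparisons of the first table. The colours end at -6 and 6.

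What part of the QKO profile needs Dux was asked with Dux-KO QKO against QKO, where 653 genes were higher and 253 lower without Dux (limma, Benjamini-Hochberg, n = 2 per group). The 2-cell program fell, with 1 of 51 higher and 41 lower (median -3.98, adjusted p = 2.68e-73), as did the Obox family, 0 of 4 higher and 3 lower (median -1.73, adjusted p = 1.8e-07). Zscan4f fell from 1898 (SD 10.8) to 0.376 TPM (SD 0.26) (log2 fold change -10.44, SE 0.142, adjusted p = 5.34e-16) and Zscan4d from 646 (SD 51.7) to 0.679 TPM (SD 0.596) (-8.64, SE 0.188, adjusted p = 8.01e-14). Obox4 fell from 774 (SD 96.4) to 40.5 TPM (SD 0.461) (-4.22, SE 0.142, adjusted p = 1.47e-11). Obox4 thus stayed above its control level of 3.93 TPM, while Zscan4d lay below its own of 6.86. Germline genes had 1 of 38 higher and 1 lower, with a median of 0.10 above 0 and a camera direction below 0 (adjusted p = 0.0606). Tex101, of that list, was higher without Dux, from 15.8 (SD 0.87) to 83.1 TPM (SD 3.34) (2.32, SE 0.126, adjusted p = 4.17e-09). Dux was listed at 0 in the Dux-KO QKO libraries, so the targeted list had 0 higher and 1 lower (median -0.07, adjusted p = 0.0182, adjusted p = 0.281 with an estimated correlation).

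Genes of the extraembryonic layers were higher in QKO cells without Dux. Genes of primitive endoderm had 14 of 19 higher and 0 lower (median 1.28, adjusted p = 9.03e-08, adjusted p = 0.261 with an estimated correlation). Gata4 rose from 15.7 (SD 1.94) to 48.1 TPM (SD 6.67) (log2 fold change 1.56, SE 0.143, adjusted p = 1.75e-06). Trophoblast genes had 8 of 16 higher and 0 lower (median 0.94, adjusted p = 2.49e-05, adjusted p = 0.0746 with an estimated correlation), with the tight junction gene Cldn4 (10.5 to 49.3 TPM, 2.12, SE 0.148) and the keratin Krt18 (13.0 to 42.5 TPM, 1.64, SE 0.173). Among imprinted genes, 2 of 30 higher and 0 lower (median 0.45, adjusted p = 0.528), H19 rose from 27.9 (SD 2) to 176 TPM (SD 3.2) (2.62, SE 0.109, adjusted p = 2e-10) and Cdkn1c (10.8 to 46.7 TPM, 2.02, SE 0.152) followed. The largest rises were those of Pnliprp2 (4.01 to 60.4 TPM, 3.62, SE 0.204) and Magea3 (5.21 to 51.8 TPM, 3.08, SE 0.159). Scaling to median ratios moved the all-gene median from 0.22 to 0.04 and the share of called genes that were higher from 72.1% to 54.5%.

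Genes that a Dux transgene induced were then traced through the first table. The Dux-induced set held the 25 genes called higher with doxycycline in the control line of the second table, a set chosen on those samples, and no library of the first table entered its choice. In Setdb1-KO 24 of 25 were higher and 0 lower (median 3.58, adjusted p = 3.21e-41), in G9a-KO 22 of 25 were higher and 0 lower (median 1.84, adjusted p = 3.01e-21) and in Suv39h1/2-DKO 0 of 25 were higher and 15 lower (median -1.53, adjusted p = 6.41e-53) by limma camera. In Suv39h1/2 Setdb1-TKO 24 of 25 were higher and 0 lower (median 2.58, adjusted p = 2.88e-33) and in G9a Setdb1-DKO 24 of 25 were higher and 0 lower (median 4.64, adjusted p = 4.88e-27). In G9a Suv39h1/2-TKO 17 of 25 were higher and 0 lower (median 1.41, adjusted p = 1.84e-18), and in QKO 24 of 25 were higher and 0 lower (median 5.73, adjusted p = 2.43e-28). Against QKO, the Dux-KO QKO libraries had 0 of 25 higher and 23 lower (median -4.95, adjusted p = 1.17e-65). Of the 25 genes, 16 also stood in the 2-cell list, Zscan4a, Zscan4b, Tcstv1, Usp17le and Tmem92 among them, and 1, Obox4, in the Obox family.

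Whether the effect of losing Setdb1 depends on G9a was tested as an interaction, and 331 genes had a more positive and 249 a more negative effect of Setdb1 loss without G9a than with it (limma on the log2 scale, n = 2 per group). With scaling to median ratios this majority turned, to 270 more positive and 289 more negative. Reg1 was at 0.0683 TPM in control, 0.231 without Setdb1, 0.656 without G9a and 51.0 without both (interaction 4.79, SE 0.281, adjusted p = 1.5e-07). Akr1c21 went the other way, at 0.948, 106, 24.5 and 145 TPM in the same order (-3.28, SE 0.207, adjusted p = 2.73e-07). Primitive endoderm genes had 0 of 19 more positive and 12 more negative (median -1.12, adjusted p = 6.31e-18, adjusted p = 0.0728 with an estimated correlation), among them Pdgfra (-2.43, SE 0.268, adjusted p = 5.44e-05) and Gata4 (-2.07, SE 0.202, adjusted p = 2.5e-05). Germline genes had 0 of 38 more positive and 8 more negative (median -0.56, adjusted p = 1.92e-13) and the Dux-induced set 0 of 25 more positive and 8 more negative (median -0.39, adjusted p = 1.26e-10). The 2-cell list moved both ways, 8 of 51 more positive and 10 more negative, 8 and 11 over the list alone (median -0.23, adjusted p = 0.00916, adjusted p = 0.437 with an estimated correlation), with Zscan4d lower (-2.21, SE 0.265, adjusted p = 0.000114).

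The same test against Suv39h1 and Suv39h2 called 21 genes with a more positive and 2 with a more negative effect of Setdb1 loss in their absence (limma, n = 2 per group). Zscan4f was at 35.3 TPM in control, 609 without Setdb1, 2.93 without Suv39h1 and Suv39h2 and 444 without all 3 (interaction 2.77, SE 0.201, adjusted p = 1.7e-05). Adm had a more negative effect (-1.70, SE 0.237, adjusted p = 0.00441). Genes of the 2-cell list had 7 of 51 more positive and 0 more negative, 10 and 0 over the list alone (median 0.23, adjusted p = 0.000135, adjusted p = 0.267 with an estimated correlation). The Dux-induced set had 7 of 25 more positive and 0 more negative, 9 and 0 over the list alone (median 0.64, adjusted p = 6.72e-15). ATF4 genes had 0 of 16 more positive and 0 more negative, 0 and 1 over the list alone (median -0.27, adjusted p = 2.39e-09). Leaving out control replicate 1 or TKO replicate 1 gave 14 called genes in place of 23, and leaving out Setdb1-KO replicate 1 or TKO replicate 2 gave 13. Scaling to median ratios moved the share that was more positive from 91.3% to 69.6%.

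In cells without G9a, Suv39h1 and Suv39h2, the effect of Setdb1 loss was more positive for 438 genes and more negative for 322 than in otherwise intact cells (limma, n = 2 per group). The 2-cell list gained, 26 of 51 more positive and 0 more negative (median 1.03, adjusted p = 1.58e-15), with Zfp352, a zinc finger gene of the 2-cell stage (log2 fold change 2.37, SE 0.241, adjusted p = 1.76e-05), and Tdpoz1 (2.696, SE 0.252, adjusted p = 7.77e-06). The Dux-induced set gained too, 14 of 25 more positive and 0 more negative (median 1.04, adjusted p = 1.29e-09). Primitive endoderm genes went the other way, 0 of 19 more positive and 16 more negative, 0 and 17 over the list alone (median -2.07, adjusted p = 2.77e-24). They included Gata4, at 12.9 TPM in control, 28.5 without Setdb1, 62.6 in G9a Suv39h1/2-TKO and 15.7 in QKO (-3.01, SE 0.202, adjusted p = 3.57e-07). Gata6 (chr18:11052064-11085635) was at 95.3 TPM in G9a Suv39h1/2-TKO and 22.8 in QKO (-2.87, SE 0.181, adjusted p = 3.51e-07). H19 (-3.23, SE 0.155, adjusted p = 1.93e-08) was also more negative, and Reg1 (4.28, SE 0.281, adjusted p = 3.57e-07) more positive. ATF4 genes had 0 of 16 more positive and 5 more negative (median -0.45, adjusted p = 7.78e-08) and the proteasome comparator 0 of 31 more positive and 0 more negative (median -0.31, adjusted p = 2.92e-08). The comparator had a smaller camera p-value than the ATF4 list, so a p-value of this size does not set a list apart here.

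The effect of G9a loss was more positive for 128 genes and more negative for 152 where Suv39h1 and Suv39h2 were also absent (limma, n = 2 per group). Line name and genotype cannot be told apart here. Zscan4f was at 35.3 TPM in control, 179 without G9a, 2.93 without Suv39h1 and Suv39h2 and 83.1 without all 3 (interaction 2.12, SE 0.201, adjusted p = 2.94e-05). 2-cell genes had 15 of 51 more positive and 0 more negative, 16 and 0 over the list alone (median 0.43, adjusted p = 4.48e-09, adjusted p = 0.0897 with an estimated correlation). The Dux-induced set had 12 of 25 more positive and 0 more negative (median 0.95, adjusted p = 1.79e-14). Primitive endoderm genes counted 0 of 19 more positive and 2 more negative, 0 and 5 over the list alone (median -0.73, adjusted p = 9.58e-12, adjusted p = 0.141 with an estimated correlation). Calcoco2 was more positive (2.09, SE 0.16, adjusted p = 4.01e-06). Rpph1, a neighbour of Pnp2, was more negative (-3.32, SE 0.605, adjusted p = 0.00556). Pnp2 was at 16.2 TPM in G9a-KO and 19.8 in Suv39h1/2-DKO, and was listed at 0 where both losses were combined.

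The second table asked how cells labelled as without endogenous Dux respond to Dux put back by doxycycline, at 2 libraries per group. The targeted genes were read first there too: without doxycycline Setdb1 was at 68.5 (SD 3.48) TPM in control and 22.6 (SD 8.83), 17.1 (SD 2.35), 21.5 (SD 9.76) and 21.8 (SD 1.34) in the Setdb1-KO, Suv39h1/2 Setdb1-TKO, G9a Setdb1-DKO and QKO lines. Ehmt2 was at 119 (SD 13.5) TPM in control and at 2.83 (SD 0.601), 4.74 (SD 2.60), 3.57 (SD 0.611) and 4.08 (SD 0.0775) in the 4 lines without G9a. Suv39h1 was at 27.9 (SD 4.001) TPM in control and at 11.7 (SD 1.04), 11.7 (SD 0.0304), 6.33 (SD 0.470) and 6.79 (SD 0.886) in the 4 lines without it. Suv39h2 was at 18.98 (SD 0.00707) in control and at 11.2 (SD 0.810), 11.5 (SD 1.19), 8.54 (SD 0.655) and 8.33 (SD 1.002) in those lines. Lower levels were not limited to lines without the gene: Setdb1 was at 36.3 (SD 8.25) in Suv39h1/2-DKO and 43.4 (SD 7.44) in G9a-KO, Suv39h1 at 16.1 (SD 0.139) in G9a-KO and Ehmt2 at 68.2 (SD 16.8) in Suv39h1/2-DKO. The transgene (TetOnDux) went with doxycycline from 3.07 (SD 0.218) to 29.2 (SD 0.287) TPM in control and from 3.62 (SD 0.376) to 34.4 (SD 21.4) in Setdb1-KO (19.3 without replicate 2, a library of high nuclear RNA), at dose label 0.2. At dose label 1 it reached 65.3 (SD 8.67) TPM in Suv39h1/2-DKO, 44.7 (SD 2.78) in Suv39h1/2 Setdb1-TKO, 56.8 (SD 1.80) in G9a-KO, 40.0 (SD 0.528) in G9a Setdb1-DKO, 40.5 (SD 11.1) in G9a Suv39h1/2-TKO and 33.7 (SD 11.8) in QKO. The MERVL-sfGFP reporter, driven by a retroviral promoter that Dux activates, lay at 29.0 (SD 5.01) TPM without and 47.7 (SD 12.4) with doxycycline in control. In the same order it lay at 38.8 (SD 7.83) and 69.0 (SD 31.2) in Setdb1-KO, 8.998 (SD 0.626) and 25.2 (SD 5.01) in Suv39h1/2-DKO, 11.5 (SD 1.37) and 23.8 (SD 8.09) in Suv39h1/2 Setdb1-TKO, 31.9 (SD 3.29) and 162 (SD 92.1) in G9a-KO, 98.7 (SD 3.37) and 196 (SD 123) in G9a Setdb1-DKO, 50.4 (SD 3.80) and 83.4 (SD 9.93) in G9a Suv39h1/2-TKO and 61.1 (SD 6.03) and 78.5 (SD 8.30) in QKO. Without replicate 2 with doxycycline, a library of high nuclear RNA, the reporter was at 96.9 TPM in G9a-KO and 109 in G9a Setdb1-DKO.

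In all, 6 libraries of the second table stood apart in nuclear RNA. The mean log2 level of Snhg small nucleolar RNA host genes was 4.46 to 4.94 in them against 2.57 to 3.49 in the other 26. Neat1, a nuclear retained RNA, was at 38.3 to 89.2 TPM against 2.13 to 5.78. They were 1 library each of the control line without doxycycline, the Setdb1-KO line without and with it, the G9a-KO line with it, and the G9a Setdb1-DKO line without and with it. All 18 libraries of the first table lay on the high side, at 4.60 to 5.22 for Snhg genes. The called genes of each doxycycline response and genotype comparison of this table are therefore counted also in the 26 libraries of low nuclear RNA alone, a split chosen after seeing the data. That fit leaves 1 library in each of these 6 groups, so n was 1 there and their spread was taken from the other groups.

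In the control line, doxycycline raised 25 genes and lowered 0 (limma, Benjamini-Hochberg, n = 2 per group), and 51 and 0 in the low nuclear RNA libraries, with 24 genes in common. Zscan4a rose from 0.594 (SD 0.0859) to 38.4 TPM (SD 6.36) (log2 fold change 4.62, SE 0.413, adjusted p = 1.86e-06, and 4.56, adjusted p = 1.83e-08, in low nuclear RNA libraries). Obox4 rose from 4.34 (SD 1.22) to 49.1 TPM (SD 7.67) (3.24, SE 0.265, adjusted p = 7.79e-07, and 3.47, adjusted p = 7.79e-08, in low nuclear RNA libraries). Zscan4f (8.05 to 138 TPM, 3.96, SE 0.47) and Tcstv1 (1.501 to 34.7 TPM, 3.84, SE 0.551) did too. 2-cell genes counted 16 of 51 higher and 0 lower, 26 and 0 over the list alone (median 1.70, adjusted p = 8.84e-86), and 27 genes higher in the low nuclear RNA libraries. The Obox family had 1 of 4 higher and 0 lower (median 0.26, adjusted p = 1.47e-07). In this comparison, 1 of the libraries without doxycycline was of the high nuclear RNA class. The count fell to 16 without that library, dox0 replicate 1, to 14 without dox0.2 replicate 1 and to 16 without dox0.2 replicate 2. Scaling to median ratios moved the all-gene median from -0.15 to -0.01.

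Setdb1-KO cells given the same dose had 23 genes higher and 0 lower with doxycycline, and 23 and 0 in low nuclear RNA libraries (1 against 1), 21 in common (limma, n = 2 per group in the first of these). Zscan4f rose from 4.09 (SD 1.58) to 186 TPM (SD 121) (log2 fold change 5.06, SE 0.47, adjusted p = 7.24e-06, and 4.67, adjusted p = 1.53e-07, at 99.9 TPM, in low nuclear RNA libraries). The 2-cell list had 16 of 51 higher and 0 lower, 22 and 0 over the list alone (median 1.57, adjusted p = 2.32e-92) with 15 higher in the low nuclear RNA libraries. The Dux-induced set, chosen at this dose in control libraries, had 18 of 25 higher and 0 lower, 23 and 0 over the list alone (median 2.63, adjusted p = 5.69e-178). Replicate 2 of both arms was of the high nuclear RNA class, and the count was 11 without dox0 replicate 1 and 8 without dox0.2 replicate 2. Tested as an interaction at the matched dose, 0 genes differed between the responses of Setdb1-KO and control (limma, 136 genes at raw p below 0.05, median SE 0.31), and 0 in low nuclear RNA libraries. The 2-cell list had a median difference of -0.05 (adjusted p = 0.00139, adjusted p = 0.932 with an estimated correlation). The Dux-induced set, which shares the control libraries, had 0 of 25 higher and 0 lower, 0 and 2 over the list alone (median -0.43, adjusted p = 2.89e-08, adjusted p = 0.54 with an estimated correlation).

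Cells without Suv39h1 and Suv39h2 had 59 genes higher and 3 lower with doxycycline at dose label 1, and 100 and 6 in low nuclear RNA libraries, 61 in common (limma, n = 2 per group). Zscan4f rose from 2.47 (SD 0.831) to 295 TPM (SD 1.75) (log2 fold change 6.43, SE 0.47, adjusted p = 4.37e-08). Grhl3 (35.9 to 14.99 TPM, -1.21, SE 0.192) and Maff (16.4 to 6.65 TPM, -1.19, SE 0.228) fell. Genes of the 2-cell list had 25 of 51 higher and 0 lower, 31 and 0 over the list alone (median 2.74, adjusted p = 9.13e-100) with 32 higher in low nuclear RNA libraries. The Dux-induced set rose with 24 of 25 higher and 0 lower, 25 and 0 over the list alone (median 4.13, adjusted p = 7.64e-170). Both arms were of the low nuclear RNA class, and the count was 34 without dox1 replicate 2. When Setdb1 was lost as well, 34 genes were higher and 0 lower, 64 and 0 in low nuclear RNA libraries with 34 in common. Zscan4f rose there from 0.983 (SD 0.235) to 234 TPM (SD 2.74) (6.89, SE 0.47, adjusted p = 3.13e-08). Its 2-cell list had 20 of 51 higher and 0 lower, 28 and 0 over the list alone (median 2.28, adjusted p = 2.12e-134) with 28 in low nuclear RNA libraries. Of the Dux-induced set, 22 of 25 were higher and 0 lower, 23 and 0 over the list alone (median 3.74, adjusted p = 4.06e-268). The interaction of doxycycline with Setdb1 loss in this line called 0 genes (limma, 81 at raw p below 0.05, median SE 0.31), and 0 in low nuclear RNA libraries. It had a 2-cell median of -0.33 (adjusted p = 1.55e-10, adjusted p = 0.642 with an estimated correlation) and a Dux-induced median of -0.48 (adjusted p = 4.72e-16, adjusted p = 0.266 with an estimated correlation).

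G9a-KO cells had 130 genes higher and 2 lower with doxycycline, and 130 and 19 in low nuclear RNA libraries (1 against 2), 110 in common (limma, n = 2 per group in the first of these). Zscan4b rose from 1.35 (SD 0.343) to 346 TPM (SD 230) (log2 fold change 7.03, SE 0.486, adjusted p = 9.73e-09, and 6.30, adjusted p = 7.8e-10, at 184 TPM, in low nuclear RNA libraries). Obox4 rose from 18.9 (SD 1.27) to 1412 TPM (SD 289) (6.13, SE 0.265, adjusted p = 1.2e-11, and 5.92, adjusted p = 1.48e-10, in low nuclear RNA libraries). 2-cell genes had 41 of 51 higher and 0 lower, 45 and 0 over the list alone (median 4.15, adjusted p = 1.54e-119), 40 higher in low nuclear RNA libraries. In the Dux-induced set 24 of 25 were higher and 0 lower (median 4.88, adjusted p = 3.65e-124). Replicate 2 with doxycycline was of the high nuclear RNA class. The count was 74 without dox0 replicate 1, 281 without dox1 replicate 1 and 73 without dox1 replicate 2.

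In G9a Setdb1-DKO cells 104 genes were higher and 41 lower with doxycycline, and 121 and 83 in low nuclear RNA libraries (1 against 1), 111 in common (limma, n = 2 per group in the first of these). Zscan4a rose from 2.77 (SD 0.253) to 414 TPM (SD 250) (log2 fold change 6.64, SE 0.413, adjusted p = 2.28e-09, and 6.05, adjusted p = 9.31e-10, at 237 TPM, in low nuclear RNA libraries). The 2-cell list had 39 of 51 higher and 0 lower, 44 and 0 over the list alone (median 3.47, adjusted p = 1.07e-120), 41 higher in low nuclear RNA libraries. The Dux-induced set had 24 of 25 higher and 0 lower (median 4.07, adjusted p = 1.68e-127). Markers of primitive endoderm had 0 of 19 higher and 5 lower, 0 and 7 over the list alone (median -0.82, adjusted p = 9.35e-07, adjusted p = 0.41 with an estimated correlation). Gata4 fell from 36.3 (SD 1.82) to 11.2 TPM (SD 1.32) (-1.61, SE 0.229, adjusted p = 0.000288, and -1.68, adjusted p = 0.0266, in low nuclear RNA libraries). Germline genes had 0 of 37 higher and 0 lower, with a median of -0.05 and a mean of -0.07 below 0 and a camera direction above 0 (adjusted p = 0.0443, adjusted p = 0.784 with an estimated correlation). Replicate 2 of both arms was of the high nuclear RNA class, and the count was 73 without dox0 replicate 1, 236 without dox1 replicate 1 and 83 without dox1 replicate 2. Scaling to median ratios moved the all-gene median from -0.22 to -0.03 and the share that was higher from 71.7% to 92.2%. The interaction of doxycycline with Setdb1 loss in the G9a line called 0 genes (limma, 835 at raw p below 0.05), against 4 more positive and 35 more negative in low nuclear RNA libraries, where 3 of the 4 groups hold 1 library, 1 without G9a Setdb1-DKO dox0 replicate 1 and 2 without dox0 replicate 2. In it the 2-cell list had a median of -0.81 (adjusted p = 0.425), and scaling moved the all-gene median from -0.24 to -0.05.

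G9a Suv39h1/2-TKO cells had 63 genes higher and 0 lower with doxycycline, and 133 and 0 in low nuclear RNA libraries, 63 in common (limma, n = 2 per group). Zscan4a rose from 4.28 (SD 1.08) to 196 TPM (SD 2.23) (log2 fold change 5.24, SE 0.413, adjusted p = 1.39e-07) and Obox4 from 33.59 (SD 0.165) to 849 TPM (SD 99.8) (4.61, SE 0.265, adjusted p = 6.45e-10). 2-cell genes counted 30 of 51 higher and 0 lower, 38 and 0 over the list alone (median 3.01, adjusted p = 1.15e-138), 41 higher in low nuclear RNA libraries. In the Dux-induced set 24 of 25 were higher and 0 lower (median 3.79, adjusted p = 1.27e-173). The count was 32 without dox0 replicate 2 and 38 without either dox1 replicate, and scaling moved the all-gene median from -0.13 to 0.00. In QKO cells 53 genes were higher and 4 lower, and 111 and 18 in low nuclear RNA libraries with 57 in common. Zscan4a rose from 4.64 (SD 0.592) to 331 TPM (SD 7.18) (5.89, SE 0.413, adjusted p = 1.71e-08). Sox7 (11.98 to 3.97 TPM, -1.40, SE 0.324) fell. The 2-cell list had 27 of 51 higher and 0 lower, 38 and 0 over the list alone (median 2.46, adjusted p = 1.44e-109), 39 higher in low nuclear RNA libraries. Of the Dux-induced set, 21 of 25 were higher and 0 lower, 23 and 0 over the list alone (median 3.48, adjusted p = 3.28e-137). Without dox0 replicate 1 the QKO count was 37 and without dox0 replicate 2 it was 35, and scaling moved the all-gene median from -0.21 to -0.02. All libraries of both lines were of the low nuclear RNA class. Between the responses of QKO and G9a Suv39h1/2-TKO 0 genes differed (limma interaction, 113 at raw p below 0.05, median SE 0.31), and 0 in low nuclear RNA libraries.

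**Figure D4:**
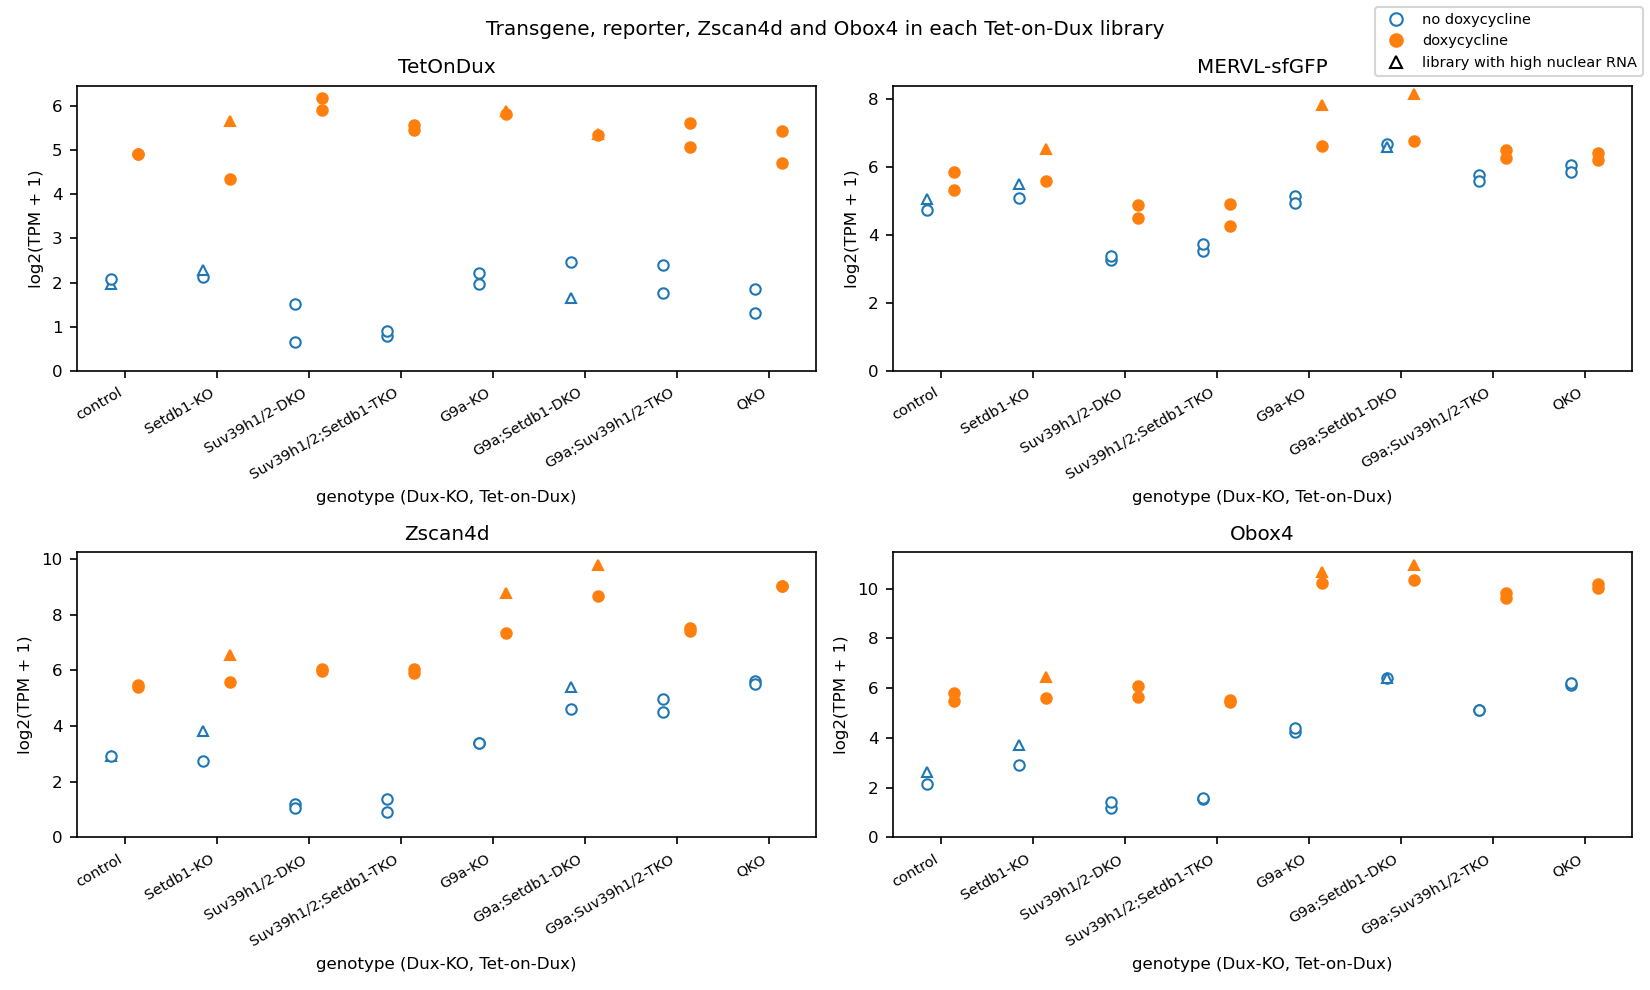
Log2(TPM+1) of the Dux transgene, the MERVL-sfGFP reporter, Zscan4d and Obox4 in each of the 32 libraries of the second table. Open blue symbols are without and filled orange symbols with doxycycline, triangles are libraries of high nuclear RNA, and n = 2 per group.

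Lines given the same dose were compared in their response to doxycycline. Between G9a-KO and Suv39h1/2-DKO 2 genes responded more in G9a-KO and 0 less (limma interaction, 338 at raw p below 0.05, n = 2 per group), against 20 and 3 in low nuclear RNA libraries. The 2-cell list counted 0 of 51 more positive and 0 more negative, 10 and 0 over the list alone (median 1.14, adjusted p = 5.91e-18, adjusted p = 0.45 with an estimated correlation), with 5 higher and 0 lower in low nuclear RNA libraries. The Dux-induced set counted 2 of 25 more positive and 0 more negative, 6 and 1 over the list alone (median 0.86, adjusted p = 1.31e-06, adjusted p = 0.614 with an estimated correlation). The G9a-KO arm held 1 library of the high nuclear RNA class, dox1 replicate 2. Leaving out G9a-KO dox1 replicate 1 gave 45 called genes, and leaving out any 1 of the other 7 libraries gave 0. With scaling to median ratios the share that was higher moved from 100% to 85.7%. Between G9a Suv39h1/2-TKO and Suv39h1/2-DKO 0 genes differed (limma interaction, 159 at raw p below 0.05), against 18 and 4 in low nuclear RNA libraries and 2 without G9a Suv39h1/2-TKO dox1 replicate 2. Of the 2-cell list 0 of 51 were more positive and 0 more negative, 3 and 1 over the list alone. No line of the other dose was compared, so the responses of control and Setdb1-KO cells stand apart from the other 6.

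Without doxycycline the second table repeats the genotype comparisons in cells labelled as without endogenous Dux. There Setdb1-KO had 231 genes higher and 117 lower than control (limma, n = 2 per group). Genes of the 2-cell list had 0 of 51 higher and 0 lower (median 0.11, adjusted p = 0.274). Germline genes rose, 22 of 37 higher and 0 lower, 23 and 0 over the list alone (median 1.15, adjusted p = 1.25e-24). Tex101 went from 1.59 (SD 0.348) to 30.8 TPM (SD 0.057) (log2 fold change 3.63, SE 0.3, adjusted p = 2.24e-07). The largest rise was that of Mep1b, from 9.41 (SD 0.183) to 178 TPM (SD 68.8) (4.05, SE 0.318, adjusted p = 1.29e-07). Msc (16.9 to 1.25 TPM, -2.99, SE 0.25) fell. p53 targets counted 3 of 20 higher and 0 lower (median 0.64, adjusted p = 2.84e-11, adjusted p = 0.0691 with an estimated correlation). Each arm held 1 library of the high nuclear RNA class.

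Suv39h1/2-DKO cells without doxycycline had 33 genes higher and 182 lower (limma, n = 2 per group). ATF4 genes rose, 2 of 17 higher and 0 lower, 4 and 0 over the list alone (median 0.90, adjusted p = 4.24e-13). Chac1 rose from 10.7 (SD 0.928) to 57.5 TPM (SD 0.157) (log2 fold change 2.33, SE 0.264, adjusted p = 4.29e-05). Herpud1 (15.1 to 59.7 TPM, 1.92, SE 0.16) rose too. Pnp2 was at 20.4 TPM in control and listed at 0 in both libraries, and Lincenc1 (60.3 to 11.98 TPM, -2.27, SE 0.306) fell. 2-cell genes had 0 of 51 higher and 4 lower (median -0.43, adjusted p = 0.089). The Dux-induced set, chosen with these control libraries, had 0 of 25 higher and 5 lower, 0 and 8 over the list alone (median -0.51, adjusted p = 0.00496, adjusted p = 0.876 with an estimated correlation). The control arm held 1 library of high nuclear RNA, dox0 replicate 1, without which 118 genes were called, and 116 were without Suv39h1/2-DKO dox0 replicate 1. Scaling moved the all-gene median from -0.15 to -0.04 and the share that was higher from 15.3% to 32.8%. When Setdb1 was lost as well, 159 genes were higher and 323 lower. Germline genes counted 12 of 37 higher and 1 lower, 12 and 2 over the list alone (median 0.66, adjusted p = 3.04e-13). The 2-cell list had 0 of 51 higher and 9 lower, 1 and 11 over the list alone (median -0.57, adjusted p = 0.0716). Mep1b (9.41 to 105 TPM, 3.34, SE 0.318) rose and Pnp2 was listed at 0 in both libraries. Scaling moved the all-gene median from -0.14 to -0.03 and the share that was higher from 33% to 47.5%.

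In G9a-KO cells without doxycycline 424 genes were higher and 678 lower (limma, n = 2 per group). Magea8 rose from values listed at 0 to 128 TPM (SD 14.5). Ehmt2 (119 to 2.83 TPM, log2 fold change -4.98, SE 0.323) and Stag3 (25.3 to 3.48 TPM, -2.57, SE 0.34) fell. 2-cell genes counted 7 of 51 higher and 0 lower (median 0.43, adjusted p = 3.4e-05, adjusted p = 0.876 with an estimated correlation). Primitive endoderm genes counted 5 of 19 higher and 0 lower (median 0.75, adjusted p = 8.16e-07, adjusted p = 0.409 with an estimated correlation). The control arm held the library of high nuclear RNA, and scaling moved the all-gene median from -0.15 to -0.01 and the share that was higher from 38.5% to 51.4%. Meg3 and Rian, which rose in the first table, were not called in any line without G9a here. Meg3 was at 0.365 and 2.44 TPM in control (0.0330 and 2.29 with doxycycline), split as Snrpn was (1.06 and 63.4 TPM), and between the 2 in G9a-KO, at 0.777 and 0.795 (-0.28, SE 0.775, adjusted p = 0.828). Meg3 means were 4.08 TPM in G9a Suv39h1/2-TKO (1.23, SE 0.775, adjusted p = 0.304) and 3.02 in QKO (0.89, SE 0.775, adjusted p = 0.407). With Suv39h1 and Suv39h2 lost as well 413 genes were higher and 500 lower. Pnp2 fell from 20.4 (SD 0.406) to 0.0924 TPM (SD 0.00588) (-4.29, SE 0.18, adjusted p = 8.17e-13). The 2-cell list had 21 of 51 higher and 0 lower (median 1.05, adjusted p = 3.39e-12, adjusted p = 0.576 with an estimated correlation). There scaling moved the share that was higher from 45.2% to 54.3%.

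G9a Setdb1-DKO cells without doxycycline had 1015 genes higher and 812 lower (limma, n = 2 per group). In these cells, labelled as without endogenous Dux, the 2-cell list had 35 of 51 higher and 0 lower, 37 and 0 over the list alone (median 1.80, adjusted p = 7.71e-13, adjusted p = 0.56 with an estimated correlation). Akr1c21 rose from 0.633 (SD 0.168) to 194 TPM (SD 47.2) (log2 fold change 6.89, SE 0.37, adjusted p = 2.7e-11). Gpc3 (52.4 to 2.82 TPM, -3.79, SE 0.206) fell. Germline genes counted 19 of 37 higher and 3 lower (median 1.11, adjusted p = 2.7e-07, adjusted p = 0.21 with an estimated correlation). p53 targets counted 11 of 20 higher and 0 lower (median 1.04, adjusted p = 2.89e-08, adjusted p = 0.174 with an estimated correlation). Each arm held 1 library of high nuclear RNA.

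QKO cells without doxycycline had 910 genes higher and 1025 lower (limma, n = 2 per group). Their 2-cell list had 32 of 51 higher and 0 lower (median 1.86, adjusted p = 1.88e-14, adjusted p = 0.54 with an estimated correlation). Its median was 1.904 in low nuclear RNA libraries, against 1 control library. Akr1c21 rose from 0.633 (SD 0.168) to 174 TPM (SD 7.47) (log2 fold change 6.74, SE 0.37, adjusted p = 3.5e-11), and Pnp2 (20.4 to 0.143 TPM, -4.23, SE 0.18) fell. Germline genes counted 18 of 37 higher and 3 lower (median 1.07, adjusted p = 6.48e-08, adjusted p = 0.179 with an estimated correlation). Trophoblast genes had 10 of 17 higher and 0 lower (median 1.24, adjusted p = 1.03e-05, adjusted p = 0.0619 with an estimated correlation). The control arm held the library of high nuclear RNA, and scaling moved the all-gene median from -0.11 to 0.00 and the share that was higher from 47% to 56.2%.

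The 2 tables share no library, so the genotype effects were compared gene by gene over the 13416 genes tested in both, as a description (Fisher's exact test, n = 2 per group). Genes higher in both tables, against the number expected from the margins, were 176 against 9.56 (exact p = 4.23e-204) for Setdb1-KO, 293 against 23.1 (exact p = 4.63e-290) for G9a-KO, 102 against 7.54 (exact p = 1.32e-96) for Suv39h1/2 Setdb1-TKO and 248 against 19.2 (exact p = 8.04e-239) for G9a Suv39h1/2-TKO. They were 696 against 95.4 for G9a Setdb1-DKO and 608 against 91.3 for QKO, and 1 against 0.0439 (exact p = 0.043) for Suv39h1/2-DKO. Genes lower in both numbered 61 against 2.40 (exact p = 1.07e-73) for Setdb1-KO, 8 against 0.713 (exact p = 4.94e-07) for Suv39h1/2-DKO, 274 against 25.1 (exact p = 1.88e-238) for G9a-KO and 74 against 7.16 (exact p = 5.97e-55) for Suv39h1/2 Setdb1-TKO. For G9a Setdb1-DKO, G9a Suv39h1/2-TKO and QKO they numbered 359 against 38.2 (exact p = 2.61e-294), 152 against 10.2 (exact p = 1.25e-149) and 385 against 54.8 (exact p = 1.12e-257). Correlations of log2 fold changes across genes were 0.651, 0.186, 0.693, 0.427, 0.756, 0.673 and 0.684 for Setdb1-KO, Suv39h1/2-DKO, G9a-KO, Suv39h1/2 Setdb1-TKO, G9a Setdb1-DKO, G9a Suv39h1/2-TKO and QKO. Columns of both tables share line names, so overlap cannot set losses other than Setdb1 apart from line differences.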

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

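These interactions were written as tests before the data were examined, and their sizes were singled out after seeing the result. The effect of Setdb1 loss differed between cells with and without G9a for 580 genes, between cells with and without Suv39h1 and Suv39h2 for 23 genes, and between intact cells and cells without all of G9a, Suv39h1 and Suv39h2 for 760 genes (limma, n = 2 per group). The effect of G9a loss differed between cells with and without Suv39h1 and Suv39h2 for 280 genes. The response to doxycycline differed between G9a-KO and Suv39h1/2-DKO cells for 2 genes.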

How the results depend on the processing

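The settings below were fixed before the data were examined, except the low nuclear RNA libraries, the nuclear RNA class as a term and the 2 settings based on Snrpn, which were chosen after seeing the result. Counts of called genes that moved by over 1.5 times are listed per comparison, where the cause was not tested. With a pseudocount of 0.1 they were 1654 (Setdb1-KO), 193 (Suv39h1/2-DKO), 2320 (G9a-KO), 1756 (Suv39h1/2 Setdb1-TKO), 3014 (G9a Setdb1-DKO), 1722 (G9a Suv39h1/2-TKO) and 1552 (Dux-KO QKO against QKO), 53 and 426 (240 more positive and 186 more negative, the other way round from the text) for the interactions of Suv39h1/2 loss with Setdb1 and with G9a loss, 226 (95 higher and 131 lower, also turned) and 87 (53 and 34) for doxycycline in G9a Setdb1-DKO and QKO, 352, 1693, 805 and 1418 without doxycycline in Suv39h1/2-DKO, G9a-KO, Suv39h1/2 Setdb1-TKO and G9a Suv39h1/2-TKO, and 0 for the doxycycline response of G9a-KO against Suv39h1/2-DKO, where the Dux-induced set turned to a median of -0.0302. Without a filter on low values the Suv39h1/2 by Setdb1 interaction called 15 genes, and doxycycline by Setdb1 loss in the G9a and Suv39h1/2 line 2. Scaling by median ratios gave 39 genes for doxycycline in control, 7 for G9a-KO against Suv39h1/2-DKO and 2 for G9a Suv39h1/2-TKO against Suv39h1/2-DKO. With the replicate block the Suv39h1/2 by Setdb1 interaction called 38 genes and the response of G9a Suv39h1/2-TKO against Suv39h1/2-DKO 2, and the block moved no other count by over 1.5 times. Same-numbered replicates did not deviate together in every pair of groups (correlations -0.0585 to 0.622 in the first table, 25 of 36 pairs over 0.1, and -0.647 to 0.748 in the second, 66 of 120), so the numbers were not taken as pairs. In replicates 1 and 2 of the second table Snrpn lay at 1.06 and 63.4 TPM in control and, crossed, 60.4 and 0.690 in Setdb1-KO without doxycycline (0.9996 and 61.2, and 61.2 and 1.24, with it). A block paired by Snrpn and the Snrpn class as a term moved no count by over 1.5 times. The term turned the majority without doxycycline in G9a Suv39h1/2-TKO (445 higher against 413) and QKO (1027 higher against 850). Low nuclear RNA libraries alone gave 51 (control), 106 (Suv39h1/2-DKO), 64 (Suv39h1/2 Setdb1-TKO), 133 (G9a Suv39h1/2-TKO) and 129 (QKO) genes for doxycycline, 39 for doxycycline by Setdb1 loss in the G9a line, 23 for G9a-KO against Suv39h1/2-DKO and 22 for G9a Suv39h1/2-TKO against Suv39h1/2-DKO, and turned primitive endoderm genes (0.0617) and proteasome genes (0.00272) in the doxycycline by Setdb1 interaction of the control line. The nuclear RNA class as a term gave 65 (control), 41 (Setdb1-KO), 105 (Suv39h1/2-DKO), 57 (Suv39h1/2 Setdb1-TKO), 241 (G9a Setdb1-DKO), 105 (G9a Suv39h1/2-TKO) and 123 (QKO) for doxycycline, and 1, 8 and 5 for the same 3 interactions, and turned the majority to higher genes without doxycycline in G9a-KO (551 against 536), G9a Suv39h1/2-TKO (576 against 416) and QKO (1155 against 846). Of the 14 overlaps between the tables, 10 moved with a pseudocount of 0.1 and 14 when genes were called by adjusted p alone, with 485 and 783 genes higher in both for G9a-KO. With 1 library left out, the ranges were 13 to 31 for the Suv39h1/2 by Setdb1 interaction, 14 to 19 (control), 8 to 24 (Setdb1-KO), 34 to 65 (Suv39h1/2-DKO), 73 to 281 (G9a-KO), 73 to 236 (G9a Setdb1-DKO), 32 to 45 (G9a Suv39h1/2-TKO) and 35 to 42 (QKO) for doxycycline, 116 to 296 for Suv39h1/2-DKO without doxycycline, 0 to 45 for G9a-KO against Suv39h1/2-DKO, 0 to 2 for G9a Suv39h1/2-TKO against Suv39h1/2-DKO and 0 to 2 for doxycycline by Setdb1 loss in the G9a line, where the library left alone in its group was taken to vary like the other groups. Of 528 list tests camera called 213, of which an estimated correlation lost 151 and kept 62, and fry turned germline genes in the doxycycline response of G9a Setdb1-DKO (-0.0483).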

Other observations

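The comparison of Dux-KO QKO with control cells, and the tests of the 3 patterns in the paragraphs after it, were chosen after seeing the result. Cells without these enzymes and without Dux differed from control cells in 2335 genes that were higher and 597 that were lower (limma, Benjamini-Hochberg, n = 2 per group). Akr1c21 rose from 0.948 (SD 0.389) to 454 TPM (SD 5.52) (log2 fold change 7.88, SE 0.146, adjusted p = 1.51e-14), with Reg1 (0.0683 to 194 TPM, 7.51, SE 0.198) and Magea8 (0.0258 to 133 TPM, 7.03, SE 0.131). p53 targets had 17 of 20 higher and 0 lower (median 1.76, adjusted p = 2.44e-08, adjusted p = 0.0971 with an estimated correlation), trophoblast genes 11 of 16 higher and 1 lower (median 1.68, adjusted p = 8.25e-05, adjusted p = 0.0971 with an estimated correlation) and primitive endoderm genes 16 of 19 higher and 0 lower (median 1.87, adjusted p = 2.77e-07, adjusted p = 0.208 with an estimated correlation). Germline genes had 29 of 38 higher and 1 lower (median 1.95, adjusted p = 1.31e-08, adjusted p = 0.0971 with an estimated correlation) and imprinted genes 17 of 30 higher and 2 lower (median 1.03, adjusted p = 3.93e-05, adjusted p = 0.196 with an estimated correlation). The proteasome comparator had 0 of 31 higher and 1 lower (median -0.33, adjusted p = 2.77e-07, adjusted p = 0.0362 with an estimated correlation) and ATF4 genes 4 of 16 higher and 4 lower (median -0.57, adjusted p = 0.00572, adjusted p = 0.196 with an estimated correlation). With an estimated correlation the comparator was the only list below 0.05 by camera. The list p-values of this comparison therefore do not set the other lists apart from the comparator. Although Dux was listed at 0, the 2-cell list had 29 of 51 higher and 5 lower (median 1.33, adjusted p = 0.00215, adjusted p = 0.286 with an estimated correlation), with Sp110 (0.0986 to 16.3 TPM, 3.97, SE 0.193) and Zfp352 (0.549 to 11.8 TPM, 3.05, SE 0.17) higher, while the Dux-induced set had 9 of 25 higher and 7 lower (adjusted p = 0.377).

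Of the libraries with Tet-on-Dux, 6 carried high nuclear RNA, with 193 genes more than 1 log2 unit higher than in their replicate in all 6 and 0 lower. An effect of genotype or doxycycline could not account for it, since all 6 had a replicate of the same group in the low class. A shared library or culture batch and a transcript length bias (Spearman rho 0.232 over 13291 genes) stay open. The lowest of 15 correlations of replicate differences (0.452) cannot decide, as libraries were picked for a shared profile. In control and Setdb1-KO lines the high class also had low Snrpn, at 0.690 to 1.24 TPM against 60.4 or more in replicates. A low class control library with doxycycline did too (0.9996). These replicates thus differed in more than nuclear RNA.

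Pnp2 was at or near 0 in G9a Suv39h1/2-TKO, QKO and Dux-KO QKO cells of the first table and in all lines without Suv39h1 and Suv39h2 of the second. Loss of these enzymes could not be the cause by itself, since the Suv39h1/2-DKO cells of the first table held 19.8 TPM. Reads passing to the overlapping gene Pnp stay open: against control its log2 fold change was at or below 0 in 3 of 7 comparisons of lines without Pnp2, and went from -1.17 (SE 0.227) in Suv39h1/2-DKO of the second table to 0.78 (SE 0.074) in QKO of the first. Genes within 1 Mb had medians of -0.381, -0.567 and -0.643 in 3 comparisons against 0.0312, -0.144 and 0.0518 for other genes. Of them, 12 of 14, 13 of 15 and 14 of 15 lay below 0. Partial loss of a wider chromosome 14 region in a founder clone thus stays open, and the medians argue only against its full loss.

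Members of the 2-cell list were called higher without doxycycline in G9a-KO (7 of 51, adjusted p = 0.876 with an estimated correlation), G9a Suv39h1/2-TKO (21, adjusted p = 0.576), G9a Setdb1-DKO (35, adjusted p = 0.56) and QKO (32, adjusted p = 0.54), lines labelled as without endogenous Dux. A leak of the transgene might be the cause: TetOnDux lay at means of 3.26, 3.36, 3.32 and 2.06 TPM in G9a-KO, G9a Suv39h1/2-TKO, G9a Setdb1-DKO and QKO against 3.07 in control, which leaves a stronger response to a like leak open. Of the 32 members higher in QKO, 22 were also higher in Dux-KO QKO than in control cells and so can rise without Dux. A leak stays open for all 32. Of the other 10, 5 were lower in Dux-KO QKO, such as Zscan4d (0.679 against 6.86 TPM, and 46.3 against 6.55 in QKO with the transgene). Reads shared between near-identical copies may add to it, but of 10 list members outside these families 4 were higher in QKO cells, Zfp352 (log2 fold change 2.40, SE 0.521, adjusted p = 0.00124), Zfp750, Ddit4l and Slc34a2. Loss of H3K9 dimethylation at these genes themselves is a hypothesis that no measurement here tests, and maps of this mark at them in the same lines would decide it.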
